A study of Mus musculus with 8 samples.

How the data were processed

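RNA from primitive erythroid precursors of the mouse yolk sac at embryonic day 9.5 was measured on 8 Affymetrix expression arrays, 4 labelled KLF2 knockout and 4 wild type on the FVB/N strain. Per the labels' protocols, erythroid cells were cut by laser capture from stained frozen sections of 8 micrometres. Each knockout replicate held 3600 to 4400 cells, and each replicate drew on between 2 and 4 yolk sacs from 2 litters. RNA was amplified by two-cycle labelling from 10 to 20 ng in the knockout group and 10 to 39 ng in the wild-type group, per the labels' protocols. Between 30 and 80 slides were used per knockout sample and between 12 and 50 per wild-type sample. The sample labels and the series' design text disagree on whether the dams of the knockout embryos were homozygous or heterozygous. The strain of the KLF2 line is not given in the sources used here, so strain and genotype cannot be separated.

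The authors deposited 1 log2 expression value per probe set and array, in a table of values normalised by the authors. The submitters' processing notes name GCOS, RMA (robust multi-array average) and the affy package, with no version and no stated order. The deposited values had similar medians on every array, with upper quartiles from 6.79 to 7.17, and were not compared with values recomputed by RMA. The authors also deposited a table that gives, per probe set, a signed score called an S-score with a p-value and a q-value. The file header does not state the direction of the score. It was taken from the data: the score correlated positively with the log2 difference of the labelled knockout minus wild type, so a positive score is read as higher in the arrays labelled knockout. How the score was computed is not given in the sources used here.

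The value table held 22626 probe sets and 0 control probe sets, so a planned comparison of 3 prime and 5 prime control signals, a measure of RNA integrity, could not be run. The platform annotation gave 20380 probe sets 1 gene symbol, 691 several symbols and 1555 none, and the last are unnamed here. Symbols were checked through gene identifiers against a gene table of the GRCm38.p6 assembly, which matched 20351 of the probe sets with 1 symbol and altered none of their names. A gene was represented by its probe set with the highest mean over all arrays, which gave 12393 genes.

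Values were used as deposited, with no further normalisation and no filter on dim probe sets. Groups were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on all 8 arrays, no covariate and Benjamini-Hochberg adjustment. Calls were made at an adjusted p under 0.05, and 0.05 was also the limit for unadjusted p-values and for the authors' q-values. Differences are the arrays labelled knockout minus wild type on the log2 scale. The groups share no replicate number and the labels give no batch, so the fit had neither a block nor a batch term. Of 28 gene lists, each was tested against all other genes with camera at a preset correlation of 0.01. An estimated correlation was run beside it, and fry, which tests a list against no change and not against the other genes. Single values were compared by an exact two-sided permutation test of 4 against 4 arrays, whose smallest possible p is 0.0286. The number of arrays limits the precision of every value, and the replicates are labelled as biological.

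The gene lists, the comparisons, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named Klf2, the globin genes and the Klf family. It also named, per direction, 12 genes past the threshold with the largest change, whose groups did not overlap and whose brighter group's mean reached the median of all genes. Places left empty went to the genes of smallest p under the same conditions. Up to 4 genes of smallest p were taken from each list. All 24 places were filled this second way. Reln, Adcy7 and Cd24a were put in lists knowing that the study had followed them up, so their counts are not independent evidence. Genes named from the authors' deposited table, and 3 lists of placental, decidual and neural genes, were chosen after their values were seen.

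The fit was tested on simulated data with 12393 genes and independent noise of the size found between these arrays. With 200 genes planted, it recovered 57 of 100 genes changed 2-fold and 89 of 100 changed 4-fold, with 5 false calls. It made 0 calls with no gene changed, by limma. Genes that vary together were not simulated, so these rates and counts may not hold for the real arrays. The alternatives were quantile normalisation, centring on each array's median, leaving out probe sets below the median mean, eBayes with trend and robust fitting, array weights, the mean over a gene's probe sets, a count of non-overlapping groups, and leaving out each array in turn. Leaving out wild-type arrays 3 and 5 together, and the estimated correlation under each alternative, were added after the data were seen. Figures were drawn with Python 3.11.15.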

Results

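Gene expression was measured in primitive erythroid precursors, the nucleated red cell precursors that the yolk sac makes, on 4 arrays labelled KLF2 knockout (replicates 11, 12, 13 and 14) and 4 wild-type arrays (replicates 3, 5, 7 and 9). KLF2 is a zinc finger transcription factor related to KLF1, a main regulator of red cell genes. The comparison asks which genes depend on KLF2 in these cells at embryonic day 9.5. The median log2 value per array lay between 5.08 and 5.20, and values ran from 2.47 to 14.17.

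The arrays did not fall into the labelled groups. Pearson's r over all 22626 probe sets averaged 0.965 between arrays labelled knockout (0.951 to 0.987), 0.974 between wild-type arrays (0.967 to 0.985) and 0.968 between groups (0.953 to 0.988). The mean within groups exceeded the mean between groups by 0.00147, and 11 of the 35 possible splits gave as large a difference (exact p = 0.314). For 4 arrays the closest array belonged to the other group. Wild-type arrays 3 and 5 resembled each other (r = 0.984) and stood apart from the rest on the first principal component, which held 33.1% of the variance. Knockout array 14 stood apart on the second (24.4%) and knockout array 13 on the third (18.4%).

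**Figure D1:**
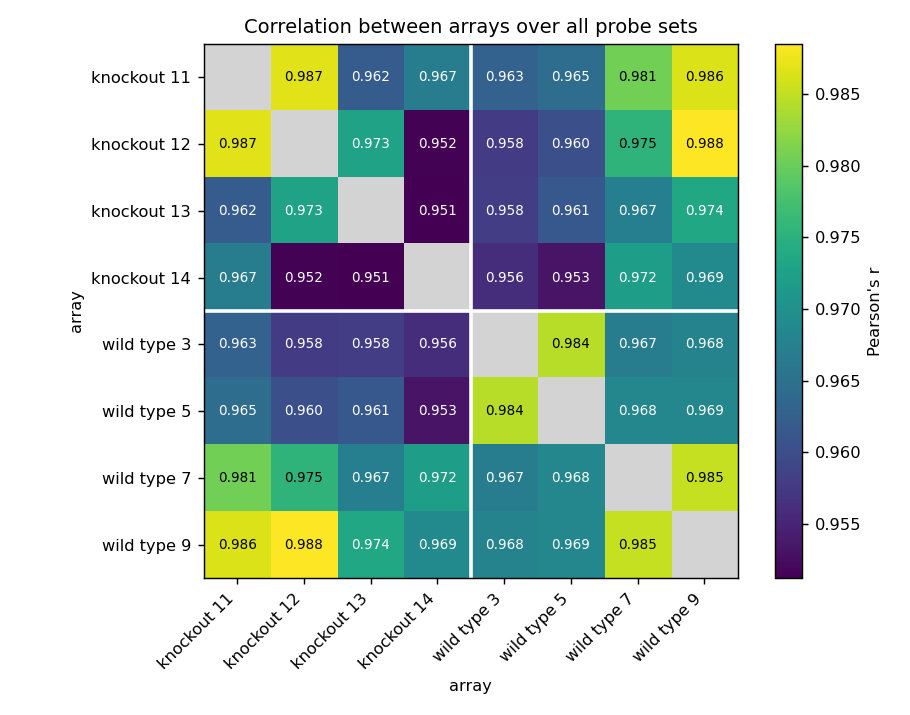
Pearson's r between each pair of the 8 arrays over all probe sets, by colour and as printed values, with white lines between the groups. Knockout array 12 and wild-type array 9 form the most similar pair, and wild-type arrays 3 and 5 are closer to each other than to the rest.

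Klf2 itself was not lower in the arrays labelled knockout. Its single probe set averaged 6.05 ± 0.77 (SD, n = 4) in them and 5.28 ± 0.31 (SD, n = 4) in wild type, a log2 difference of 0.77 (SE 0.35, exact permutation p = 0.0571). Without knockout array 13 the difference was 0.40, and it was 0.99 without knockout array 11 and 0.91 without wild-type array 9, where limma's unadjusted p fell below 0.05. The values were 5.38, 5.77, 7.15 and 5.89 in knockout replicates 11 to 14 and 5.18, 5.28, 4.97 and 5.70 in wild-type replicates 3, 5, 7 and 9. In wild type the probe set ranked at percentile 44.5 of all genes. Where this probe set lies relative to the deleted part of the gene is not given in the sources used here, so it cannot check the labels, and groups are named by their labels throughout.

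No single gene passed the test. The genes named here are those of smallest p whose groups did not overlap, up to 12 per direction, each by its probe set of highest mean. Among those higher in all 4 arrays labelled knockout were Esm1, Cldn5, Gpr182 and Unc5b. Esm1, which encodes the secreted proteoglycan endocan, was at 6.24 ± 0.77 (SD, n = 4) against 4.19 ± 0.38, a wild-type level whose distance from background is not given in the sources used here. It reached 7.38 in knockout array 13 and at most 5.96 in the others. Cldn5, a tight junction protein of endothelium, was 2.48-fold higher (7.67 ± 0.33 against 6.36 ± 0.48). The receptor gene Gpr182 differed by 0.76 (SE 0.14) and Unc5b, a netrin receptor, by 0.56 (SE 0.13). Adcy7, which encodes an adenylate cyclase, was 2.62-fold lower, at 6.95 ± 0.64 against 8.34 ± 0.30. Gpr155 was 2.66-fold lower (6.69 ± 0.72 against 8.10 ± 0.59). Probe sets that do not represent their gene were left out of this choice. Some of them, such as those of Hsp90b1 (-1.30) and Alcam (-0.89), did not overlap either. These had a smaller limma p than any gene named as lower.

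The other genes named as higher differed by 0.55 to 1.13 on the log2 scale. They were Zfp207 (1.13), Hprt of purine salvage (0.98), Twsg1, a modulator of BMP signalling (0.83), Nudcd3 (0.78), the spliceosome gene Snrnp70 (0.77), Ing3 (0.71), the lysosomal mannosidase gene Man2b1 (0.66) and Tada1 (0.55). Those named as lower were Slc1a4, an amino acid transporter (-1.21), Ltn1 (-0.85), the complex I subunit gene Ndufa6 (-0.70), Ackr3 (-0.64), Ribc1 (-0.59), the RNA polymerase II subunit gene Polr2a (-0.58), Cebpzos (-0.58), Bpifb1 (-0.54), Rpap2 (-0.52) and Fam117b (-0.48). All 24 genes had the same adjusted p from limma, 0.905. Other probe sets of a gene had the opposite sign for Twsg1 (2 of 4), Zfp207 (2 of 5), Man2b1 (1 of 2) and Slc1a4 (1 of 3). The 3 probe sets of Adcy7 had the same sign, but only the named one had groups that did not overlap. The others, at lower levels, differed by -0.74 and -0.02.

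By limma, 0 of 22626 probe sets and 0 of 12393 genes passed an adjusted p of 0.05, and the lowest adjusted p was 0.860 for probe sets and 0.905 for genes. At an unadjusted p under 0.05 there were 1222 probe sets (788 higher and 434 lower), where 1131.3 would be met by chance, and 595 genes (413 higher and 182 lower), where chance gives 619.65. This closeness to chance depended on the arrays used, with 637 probe sets and 292 genes without wild-type array 3. Without wild-type array 9 there were 1962 and 1032. The groups did not overlap at 676 probe sets, 2.99% against 2.86% by chance. A difference of at least 2-fold with an unadjusted p under 0.05 was found for 86 probe sets and 41 genes.

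**Figure D2:**
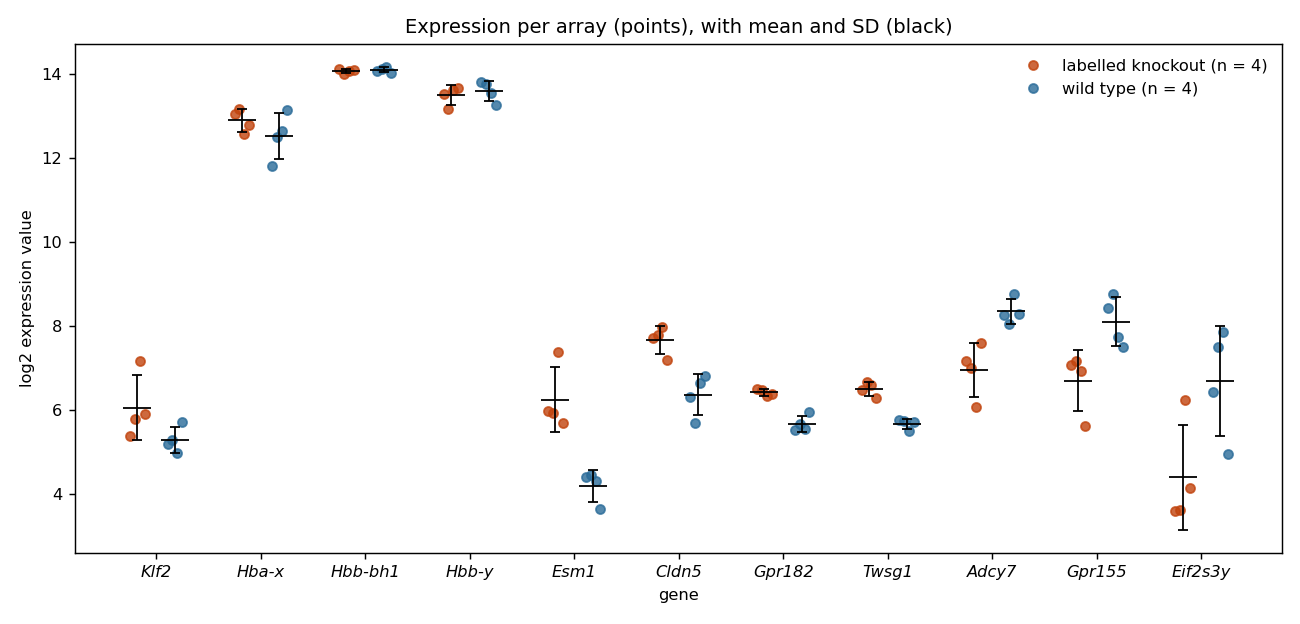
Log2 expression of 11 genes on each array labelled knockout (orange points, n = 4) and each wild-type array (blue points, n = 4), with group means and SDs in black. Embryonic globins lie near the top of the scale in both groups, while Esm1, Cldn5, Gpr182, Twsg1, Adcy7 and Gpr155 show no overlap between groups.

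Of the embryonic globins, the main product of these cells, Hbb-bh1 and Hbb-y were alike in both groups. Hbb-bh1 measured 14.08 ± 0.05 (SD, n = 4) in the arrays labelled knockout and 14.11 ± 0.06 in wild type. Hbb-y measured 13.50 ± 0.23 and 13.60 ± 0.24. The other probe sets of both genes differed by -0.05 to -0.12. These signs are not read as a direction, since Hbb-bh1 turned to 0.02 with quantile normalisation. Hba-x was at 12.90 ± 0.27 against 12.54 ± 0.55. The highest value on any array, 14.17, was that of Hbb-bh1 itself in wild-type array 7, and whether small differences can be resolved at this level was not tested. Hbb-b2, an adult beta globin gene, was at 6.15 ± 1.06 against 7.41 ± 1.18, with arrays that overlapped between the groups (adjusted p = 0.905, limma), and its second probe set differed by 0.23. The bright probe set shared by the adult beta globin genes Hbb-b1, Hbb-b2, Hbb-bs and Hbb-bt was lower on average too. It was at 11.04 ± 1.09 (SD, n = 4) against 11.99 ± 0.56, a log2 difference of -0.95 (adjusted p = 0.860, limma). Its arrays overlapped as well, at 9.64 to 12.03 in the arrays labelled knockout and 11.60 to 12.79 in wild type. In the authors' deposited table this probe set had an S-score of -3.54 at a q of 0.0435. The probe sets named for Hba-a1 and Hba-a2 alone differed by -0.02 and 0.18 at values near 4, while 3 probe sets shared by both genes were near 13 and differed by -0.08 to 0.08.

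Red cell gene groups gave no call by camera on all 8 arrays. The median difference was 0.19 for 16 haem synthesis genes (adjusted p = 0.329), 0.00 for 18 iron handling genes, 0.03 for 27 erythroid regulators, -0.02 for 23 red cell membrane genes and -0.03 for 23 KLF1-dependent genes. The adjusted p was 0.911 for iron handling and KLF1-dependent genes and 0.902 for regulators and membrane genes. Medians and means differed in sign for the last 4 of these lists. The embryonic globin list had a median of -0.03 (3 genes, adjusted p = 0.911) and the adult list -0.02 (3 genes, adjusted p = 0.748). The adult list leaves out the bright probe sets shared by several adult globin genes. Its median is that of the dim Hba-a1 probe set (3.68 against 3.69), so it says little of adult globins as a group. Among members, Snx3 differed by 0.67 (SE 0.25), Alas1 by 0.61 (SE 0.27), Jak2 by -0.59 (SE 0.22), Rb1 by -0.65 (SE 0.27) and Cd44 by 0.68 (SE 0.19). Further members of smallest p were Slc25a38 (0.54) and Alad (0.66) of haem synthesis, Steap3 (-0.42), Pcbp1 (0.52), Hmox1 (0.45) and Fth1 (-0.39) of iron handling, the regulators Foxo3 (-0.44) and Ldb1 (0.55), Bsg (0.99), Add2 (0.32), Mpp1 (0.45) and Slc4a1 (-0.43) of the membrane and the KLF1-dependent Bcl11a (0.18). None passed with adjustment over all genes, and none of these lists had a member that passed when adjusted over the list alone. Per array, haem synthesis genes lay below their mean in knockout array 13 (-0.49) and wild-type arrays 3 (-0.52) and 5 (-0.50), and above it in knockout array 14 (0.50), so the spread within groups exceeded any difference between them. Without knockout array 13, haem synthesis genes were called at a median of 0.41 (camera adjusted p = 0.00830). Without wild-type arrays 3 and 5, red cell membrane genes were called at -0.23 (camera adjusted p = 0.00125) and KLF1-dependent genes at -0.38 (camera adjusted p = 0.00274). With an estimated correlation all 3 calls were lost (camera adjusted p = 0.863 for haem synthesis and 0.739 for the others).

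The Klf and Sp family had a median difference of 0.06 over 17 genes (adjusted p = 0.748, camera). Klf1 was at 9.66 ± 0.90 (SD, n = 4) in the arrays labelled knockout and 9.83 ± 0.81 in wild type, and Klf9, Klf7 and Klf16 differed by 0.59, 0.34 and 0.34. Other family members differed by -0.32 (Klf6) to 0.40 (Klf4), all at an adjusted p of 0.905 or more by limma. Genes known to depend on KLF2 in endothelium and T cells had a median of 0.02 over 28 genes, 15 higher and 13 lower (camera adjusted p = 0.911). Such a signed test can miss members that move in opposite directions. Without regard to direction, fry gave an adjusted p of 0.765. Of the 28 genes, Cdkn1a differed by 0.72 (SE 0.31), S1pr1 by 0.39 (SE 0.20), Thbd by -0.41 (SE 0.26) and Edn1 by -0.33 (SE 0.22).

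Endothelial markers were the one list called by camera with the preset correlation. They were higher in the arrays labelled knockout by a median of 0.26 over 32 genes, 25 of them higher (adjusted p = 0.00606). Per array, the list's mean deviation was 0.18, 0.54, 0.12 and -0.28 in knockout replicates 11 to 14 and -0.30, -0.23, -0.20 and 0.17 in wild-type replicates 3, 5, 7 and 9 (exact permutation p = 0.286). The call was lost with an estimated correlation (p = 0.158, adjusted p = 0.953). The list was not called by fry either (adjusted p = 0.678), which asks whether a list's genes differ at all and not whether they differ more than other genes. Cldn5 was the single member that passed when adjusted over the list alone, and 0 passed over all genes. Esam differed by 0.83 (SE 0.28), Sox18 by 0.54 (SE 0.19) and Stab2 by 0.76 (SE 0.38). Without knockout array 12 the median was 0.16 (adjusted p = 0.310), and without wild-type array 7 it was 0.21 (adjusted p = 0.0655). With wild-type arrays 3 and 5 left out, a choice made after the data were seen, it was 0.14 (adjusted p = 0.0725).

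Markers of the other yolk sac cell types gave no call on all 8 arrays, and some gained one with arrays left out. Visceral endoderm markers, such as Mttp (-1.18, SE 0.74), had a median of -0.34 over 38 genes (adjusted p = 0.147, camera), with knockout array 14 at -1.90 from the list's mean. Without that array the list was called in the other direction, at a median of 0.21 (camera adjusted p = 0.0286). It was called as lower without knockout array 12 (-0.58, camera adjusted p = 0.00458), without knockout array 13 (-0.64, camera adjusted p = 2.9e-06) and with dim probe sets left out (-0.36, camera adjusted p = 0.0253), so no direction is drawn from it. With an estimated correlation these 4 calls were lost (camera adjusted p = 0.863 to 0.996). Other members were Krt19 (0.70), Foxa2 (-0.53) and Gata6 (0.23). Mesenchyme and mesothelium markers had a median of 0.08 over 32 genes (adjusted p = 0.865), with Sparc at 1.27 (SE 0.56) beside Lum (0.55), Bmp4 (0.75) and Twist1 (-0.21), and were called without knockout array 14 (0.38, camera adjusted p = 0.00126, lost at 0.637 with an estimated correlation). Macrophage markers had a median of 0.15 over 24 genes (adjusted p = 0.147), with Mrc1 at 0.62 (SE 0.24) beside Cd14 (0.34), Ptprc (0.49) and Adgre1 (0.34), and were called without wild-type arrays 3 and 5 (0.21, camera adjusted p = 0.0171, lost at 0.739 with an estimated correlation). For megakaryocyte and haematopoietic progenitor markers the medians were 0.09 (16 genes, adjusted p = 0.587) and 0.13 (20 genes, adjusted p = 0.584), with Itga2b at 0.77 (SE 0.33) and Cd34 at 0.76 (SE 0.32). Megakaryocyte genes next in order of p were Nbeal2 (0.26), Thbs1 (0.32) and Ppbp (-0.94), and progenitor genes Cd93 (0.49), Hhex (0.39) and Mecom (0.25).

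**Figure D3:**
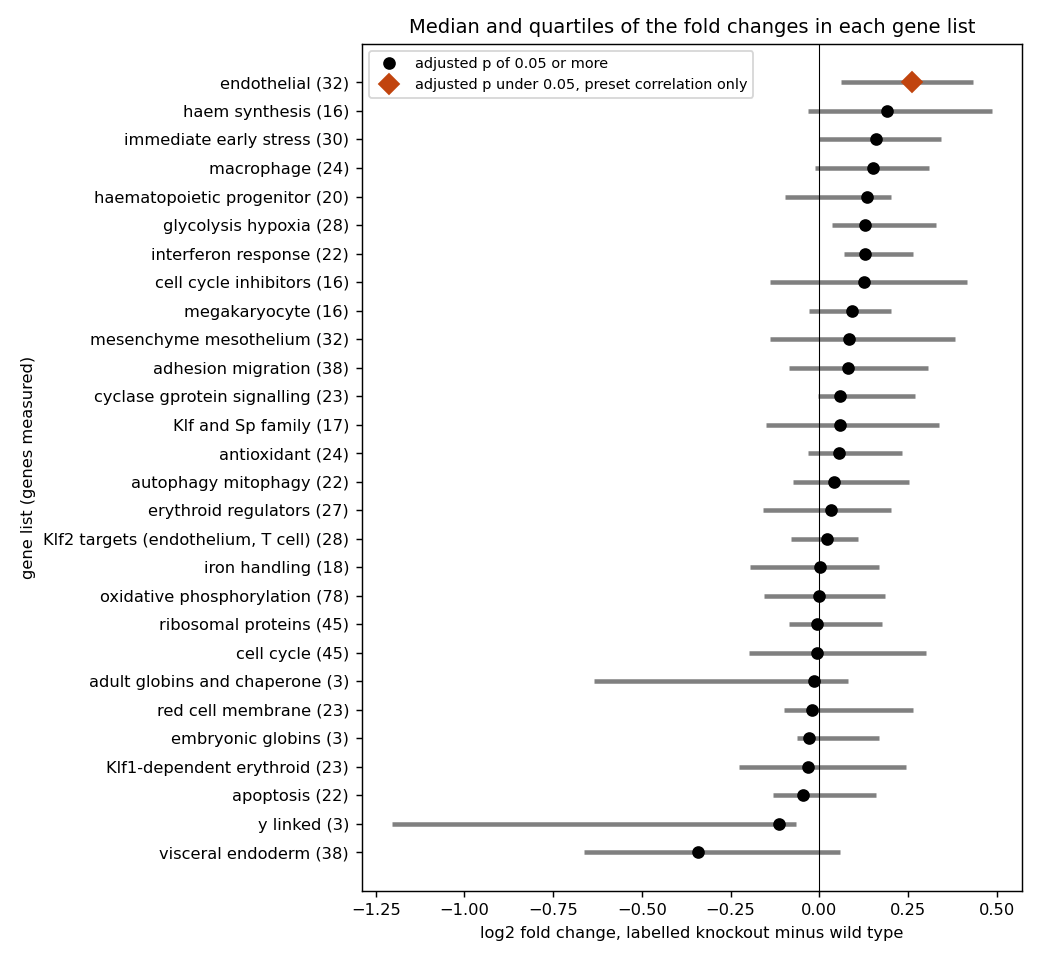
Median (points) and quartiles (bars) of the log2 fold changes, labelled knockout minus wild type, in each of the 28 gene lists, with the number of genes measured. The diamond marks the endothelial list, called with the preset correlation alone, at a median of 0.26, and visceral endoderm markers lie lowest at -0.34.

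Stress and metabolic gene groups also gave no call on all 8 arrays. Immediate early and stress genes had a median of 0.16 over 30 genes and glycolysis and hypoxia genes 0.13 over 28 genes, both with a camera adjusted p of 0.147. Ier2 differed by 0.59 (SE 0.17), and the oxygen sensors Egln1 and Egln3 by 0.61 (SE 0.19) and 0.68 (SE 0.24). Next in order of p were Aldoa (0.55) and Pkm (0.76) of glycolysis and the stress genes Ier3 (0.47), Junb (0.32) and Dnajb1 (0.35). Knockout array 13 alone lay 0.58 above the mean of the stress list. Without wild-type array 5 both lists were called (stress 0.23, glycolysis 0.20, camera adjusted p = 0.0349). Glycolysis genes were also called without knockout array 14 (0.23, camera adjusted p = 0.00352), and stress genes without wild-type arrays 3 and 5 (0.23, camera adjusted p = 0.00696). With an estimated correlation these calls were lost (camera adjusted p = 0.637 to 0.961). The interferon list (22 genes, 0.13) and the adhesion and migration list (38 genes, 0.08) had an adjusted p of 0.551, and antioxidant genes (24 genes, 0.05) one of 0.587. Autophagy genes (22 genes, 0.04) and oxidative phosphorylation genes (78 genes, 0.00) had one of 0.704. Cell cycle genes (45 genes, -0.01), cell cycle inhibitors (16 genes, 0.13), apoptosis genes (22 genes, -0.05) and ribosomal protein genes (45 genes, -0.01) had one of 0.911. Oxidative phosphorylation genes were called without wild-type arrays 3 and 5 (-0.12, camera adjusted p = 0.000467), and cell cycle genes without knockout array 13 (0.17, camera adjusted p = 0.0385). Both calls were lost with an estimated correlation (camera adjusted p = 0.739 and 0.863).

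The members of smallest p in these lists all had an adjusted p of at least 0.905 by limma. In the interferon list they were Ifit3 (-0.29), Psmb8 (0.24), Bst2 (0.32) and Irf9 (0.19), and in the adhesion list Was (0.56), Itgav (-0.84) and Cd24a (-0.68) beside Cd44. Antioxidant genes were led by Sod1 (0.49), Gss (0.50) and Keap1 (0.55) and autophagy genes by Lamp2 (-0.53), Atg16l1 (0.45), Gabarapl1 (0.61) and Gabarap (0.83). In oxidative phosphorylation they were Cox7a1 (-0.44), Atp5b (1.13) and Ndufa10 (0.73) beside Ndufa6. In the cell cycle they were Cdk2 (0.68), Ccnb2 (0.61), Aurka (0.67) and Mki67 (-0.65), and among its inhibitors Rbl1 (-0.45) and Ccng1 (-0.34) beside Rb1 and Cdkn1a. Apoptosis genes were led by Bcl2l1 (0.48), Mdm2 (0.44), Xiap (-0.42) and Apaf1 (-0.32) and ribosomal protein genes by Rpl12 (0.61), Rps4x (0.26), Rpl39 (-0.23) and Rps15 (-0.45).

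Adcy7 and Eif2s3y were the other genes past the threshold when adjusted over their list alone. In the adenylate cyclase and G protein list (23 genes, 0.06, adjusted p = 0.670), Adcy7 passed when adjusted over the list alone, and 0 genes passed over all genes. Other members were Gnai2 (0.75), Adcy6 (0.42) and Prkar1a (0.51). Adcy7 was known from the study when the list was made. Eif2s3y passed in the Y-linked list (3 genes, -0.11, adjusted p = 0.147), whose other members were Uty (-0.11) and Kdm5d (-0.02). That list was called without knockout array 13 (-0.15, camera adjusted p = 0.0385) and with the mean over probe sets (-0.20, camera adjusted p = 0.0290), and lost both calls with an estimated correlation (camera adjusted p = 0.863 and 0.943). The level of Eif2s3y was 4.39 ± 1.25 (SD, n = 4) in the arrays labelled knockout and 6.68 ± 1.30 in wild type, where the number of male and female embryos per replicate is not given in the sources used here.

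**Figure D4:**
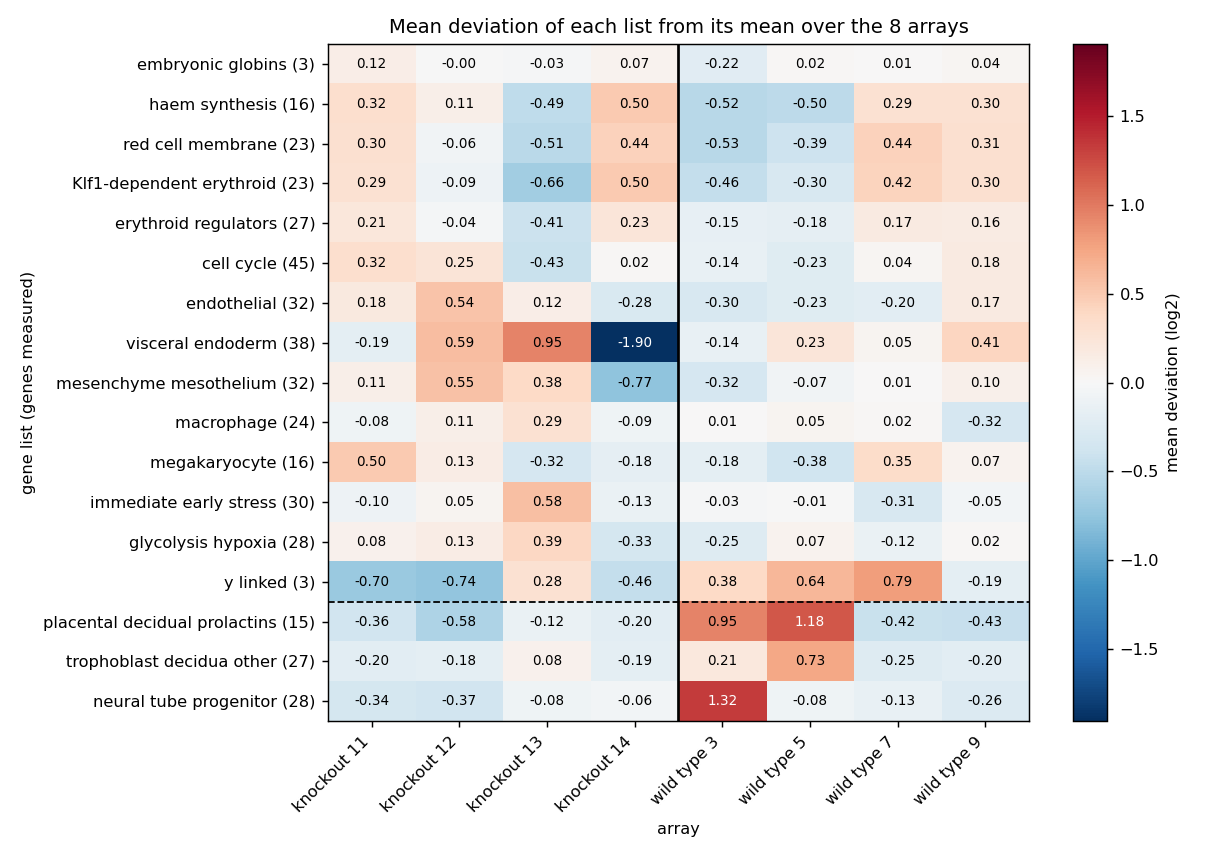
Mean deviation (log2) of each gene list from its own mean over the 8 arrays, by array, with the number of genes measured. The 3 lists under the dashed line were compiled after the values were seen. Visceral endoderm markers are low in knockout array 14 (-1.90), and neural genes are high in wild-type array 3 (1.32).

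The authors' deposited table scored 219 probe sets at a q under 0.05, of which 114 were higher and 105 lower in the arrays labelled knockout. Genes it scored higher included Ptp4a2 (S-score 6.02), the collagen chaperone gene Serpinh1 (5.97), Prpf19 (5.83), the matrix gene Sparc (5.60), Snrpb (5.57), Esm1 (5.08) and Cldn5 (3.90). Genes it scored lower included Htra1 (-7.27), the placental prolactin family genes Prl8a2 (-6.98) and Prl7a1 (-6.36), Hsp90b1 (-5.83), Eif2s3y (-5.74), Ctla2a (-5.58), Gpr155 (-5.27), Adcy7 (-5.14), Reln (-4.38) and Cd24a (-4.05). By probe sets with 1 gene symbol, the authors' deposited table scored 0 genes at this limit in the globin, haem synthesis, iron handling, erythroid regulator, red cell membrane, KLF1-dependent and Klf family lists, while the shared adult beta globin probe set was scored lower.

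Scores in the authors' deposited table and the log2 differences correlated across probe sets (Spearman's rho = 0.716), which are not independent replicates and come from the same arrays. Of the 219 probe sets in the authors' deposited table, 105 had an unadjusted limma p under 0.05, where 11.8 would be met if both were independent, and 33 had groups that did not overlap. The 105 probe sets scored lower in the authors' deposited table lay on average 1.32 and 1.47 above their mean in wild-type arrays 3 and 5, but at -0.17 and -0.35 in wild-type arrays 7 and 9. Their median difference was -1.0 against all wild-type arrays and -0.24 against arrays 7 and 9, where 76 of 105 kept their sign. The 114 scored higher in the authors' deposited table leaned on the same arrays, at -1.07 and -0.96 in wild-type arrays 3 and 5 and at -0.22 and 0.19 in arrays 7 and 9. Their medians were 0.95 and 0.48, and 112 kept their sign. Prl8a2 measured 10.87 and 11.61 in wild-type arrays 3 and 5, 3.39 and 3.45 in arrays 7 and 9, and 3.40 to 7.46 in the arrays labelled knockout. Adcy7 showed another pattern, at 8.27, 8.05, 8.77 and 8.29 in wild-type replicates 3, 5, 7 and 9 and at 6.06 to 7.59 in the arrays labelled knockout.

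**Figure D5:**
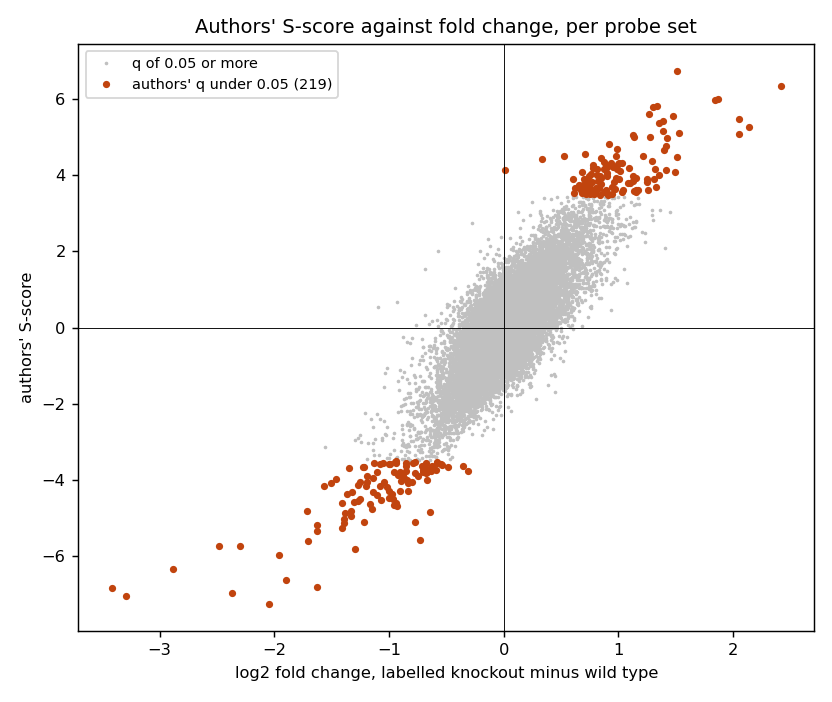
Each point is 1 probe set, with the log2 fold change of the arrays labelled knockout minus wild type on the horizontal axis and the authors' S-score on the vertical axis. The 219 orange points have an authors' q under 0.05 and share the sign of the fold change.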

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

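The tests of placental, decidual and neural genes, of the prolactin probe sets, of the endothelial shift over other splits, and both tests of endothelial markers in the second pattern were chosen after the results were seen. The test of neighbouring cell types was chosen beforehand.

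In 7 of 118 groups of 4 arrays, 1 array lay far from the other 3, where chance gives 5.9. Twsg1 was at 5.49 in wild-type array 7 and at 5.71 to 5.75 in the other wild-type arrays. Esm1 was at 7.38 in knockout array 13 and at 5.69 to 5.96 in the other knockout arrays. Man2b1 was at 5.85 in wild-type array 3 and at 6.18 to 6.24 in the other wild-type arrays. Gpr155 was at 5.61 in knockout array 14 and at 6.92 to 7.15 in the other knockout arrays. The mean deviation of the embryonic globins was -0.22 in wild-type array 3 and 0.01 to 0.04 in the other wild-type arrays. Macrophage markers deviated by -0.32 in wild-type array 9 and by 0.01 to 0.05 in the other wild-type arrays. Immediate early and stress genes deviated by -0.31 in wild-type array 7 and by -0.05 to -0.01 in the other wild-type arrays.

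In the first pattern, the 105 probe sets scored lower and the 114 scored higher in the authors' deposited table both owe much of their difference to wild-type arrays 3 and 5 (mean deviations 1.32 and 1.47, and -1.07 and -0.96), and the tests here concern the lower set alone. At all 4 prolactin probe sets in the lower set, wild-type arrays 3 and 5 lay above arrays 7 and 9. Prl8a2 was at 10.87 and 11.61 against 3.39 and 3.45, and Prl7a1 at 6.93 and 10.85 against 3.42 and 3.51. Genotype does not account for this gap, which lies within wild type. Whether genotype adds a difference beside it stays open, since these probe sets were picked after their values were seen. Arrays 7 and 9 lay below the highest knockout array at 3 of the 4, at levels below the median of all genes. At Prl7a1 they lay above all knockout arrays and 0.17 above the knockout mean (SD 0.08), also below that median. Neural tube cells in wild-type array 3 stay open. All 8 neural list genes scored lower were highest in that array, such as Sox2 (7.94, at most 3.01 elsewhere), but they are part of the pattern itself. The 18 neural genes neither seen before the list was made nor scored lower lay at percentile 98.3 of 10000 random lists matched on level. This met the rule set for them, which looked at the other wild-type arrays alone (33.0, 86.4 and 8.4 in arrays 5, 7 and 9). Knockout array 14 reached 98.1 too, so that rule was too lenient. Genes of the random lists were drawn singly, so a list whose genes vary together can reach extreme percentiles on many arrays. Haem synthesis genes, for one, lay at percentile 0 in wild-type arrays 3 and 5 and at 100 in arrays 7 and 9. Decidual or trophoblast cells in wild-type arrays 3 and 5 stay open as well. The 15 such genes chosen the same way lay at percentile 99.4 in array 5 but 44.2 in array 3, below the 90.1 of knockout array 13. Some of them, such as Ctsm (3.15 to 3.31), were low on every array, so this test had little power to show such cells. The prolactins high in arrays 3 and 5 cannot decide it, since they are part of the pattern itself. Laser capture was aimed at erythroid cells, but how much other tissue it left out was not tested, nor whether all of the 105 probe sets share a source.

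The endothelial markers that were higher in the arrays labelled knockout are the second pattern, and 12 of the 35 splits of the arrays gave a median as large in size (0.26, highest other 0.50), so chance cannot be excluded. Carry-over of neighbouring cells, which was to show as a camera call at the preset correlation, gave an adjusted p of 0.00606, but that rule was too lenient here, since the adjusted p is 0.953 with an estimated correlation and 34 of the 35 splits call at least 1 list. More endothelial cells in the captures could raise abundant markers alike. Of the 21 markers above the median level, 81.0% were higher, which met the rule written for this. The decision also asked for a camera p under 0.05 with an estimated correlation, which that rule lacked, and it was 0.158. Of the 4 most abundant markers, Lyve1 was higher (0.72, SE 0.39). Nrp1 (-0.09), Aplnr (-0.17) and Ets1 (-0.17) were lower, by less than their SE, so more endothelial cells stay an open explanation. A lower share of erythroid cells would raise visceral endoderm markers too, and the endothelial minus visceral endoderm difference of 0.56 between groups did not decide it (exact permutation p = 0.371). A response of endothelial genes to the loss of KLF2, or of strain, cannot be told apart from these.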

How the results depend on the processing

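Leaving out wild-type arrays 3 and 5, leaving out single arrays for the correlation with the authors' scores, and the estimated correlation under other settings were chosen after seeing the data; the other alternatives were planned. The counts of 0 probe sets and 0 genes by limma stayed 0 in every refit. At an unadjusted p under 0.05, counts ran from 425 probe sets and 180 genes without wild-type arrays 3 and 5 to 2544 and 1343 with array weights. With single arrays left out they ran from 637 and 292 (without wild-type array 3) to 1962 and 1032 (without wild-type array 9). Counting groups that do not overlap gave 676 probe sets, near the share that chance gives. Of the globin values, 9 of 88 changed sign, and 0 of 448 values of named genes passed the threshold. The Klf2 difference of 0.77 passed at an unadjusted limit of 0.05 with trend and robust fitting (0.77) and ran from 0.40 to 0.99 with single arrays left out, the lowest without knockout array 13; it passed without knockout array 11 or wild-type array 9.

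The number of lists called, 1, was 0 with an estimated correlation, 0 with fry, 2 with dim probe sets left out, 2 with the mean over probe sets and 5 without wild-type arrays 3 and 5. It ran from 0 to 5 with single arrays left out, with 5 lists without knockout array 13, 4 without knockout array 14, 3 without wild-type array 5 and 0 without wild-type array 7. The 5 lists without wild-type arrays 3 and 5 were red cell membrane, KLF1-dependent, macrophage, immediate early and oxidative phosphorylation genes. The endothelial median of 0.26 was not called with an estimated correlation (0.26), by fry (0.26), which tests against no change, or without wild-type arrays 3 and 5 (0.14), and ran from 0.16 to 0.40 with single arrays left out, its call lost without knockout array 12 or wild-type array 7. Of 457 values of the other lists, 17 became calls, among them visceral endoderm markers as lower without knockout array 12 or 13 and as higher without knockout array 14, and haem synthesis genes without knockout array 13. With an estimated correlation 0 of these 17 calls were left (camera, lowest adjusted p = 0.637), and 2 had an unadjusted p under 0.05. The correlation with the authors' scores was 0.839 for bright probe sets and 0.414 without wild-type arrays 3 and 5, and ran from 0.626 to 0.705 with single arrays left out. The scores were kept as deposited, so with arrays left out the scores and differences no longer rest on the same arrays. No other pair was left out for comparison. The cause of these shifts was not tested. No paired analysis was possible because the groups share no replicate number. Pseudocounts were not tried because the values are logarithms. The distance of dim probe sets from background is not given in the files used here, and limits what can be said of genes near the floor.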

Other observations

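The split counts for genes, gene lists and unadjusted p-values were chosen after the results were seen, whereas the count for probe sets and the test of genes near Klf2 were chosen beforehand.

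Single arrays differed in their makeup of cell type genes in ways that the groups do not follow. Visceral endoderm markers lay 0.95 above their mean in knockout array 13 and 0.59 above it in knockout array 12, against -1.90 in knockout array 14, where mesenchyme markers were also low (-0.77). Genes of haem synthesis, the red cell membrane and KLF1 dependence were low together in knockout array 13 (-0.49, -0.51 and -0.66) and in wild-type arrays 3 (-0.52, -0.53 and -0.46) and 5 (-0.50, -0.39 and -0.30). They were high together in knockout arrays 11 (0.32, 0.30 and 0.29) and 14 (0.50, 0.44 and 0.50) and in wild-type arrays 7 (0.29, 0.44 and 0.42) and 9 (0.30, 0.31 and 0.30). Megakaryocyte markers were high in knockout array 11 (0.50) and wild-type array 7 (0.35). The list of 15 placental and decidual prolactins lay 0.95 and 1.18 above its mean in wild-type arrays 3 and 5 and below its mean on the other arrays. Array weights from limma were lowest for knockout arrays 14 (0.410) and 13 (0.573).

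The counts of 0 probe sets and 0 genes past the adjusted threshold by limma are met by 35 of the 35 splits whatever the data, so this says nothing about chance, and 0 was also the highest other count. At an unadjusted p under 0.05, 12 of the 35 splits gave at least the 1222 probe sets of the real split, and the highest other count was 4219. That split set knockout arrays 11 and 12 and wild-type arrays 7 and 9 against the rest, which points to a structure of the arrays that crosses the groups. Values were spread more widely in the former, with lower quartiles of 3.86 to 4.00 and upper quartiles of 6.92 to 7.17. In the rest the quartiles were 4.05 to 4.13 and 6.79 to 6.88. Whether this structure comes from the samples or from the signal was not tested. For lists called by camera with the preset correlation, 34 of the 35 splits gave at least the 1 of the real split, and the highest other count was 13, so chance cannot be excluded.

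A segment of the parental strain that stayed with the altered Klf2 allele could make genes near Klf2 differ between groups. Among the 100 measured genes nearest to Klf2, 50 on each side in the order of the GRCm38.p6 assembly, 8 had an unadjusted p under 0.05, a share of 8% against 4.78% of 12268 other genes. The odds ratio was 1.73 with a 95% confidence interval from 0.72 to 3.58 (one-sided Fisher's exact p = 0.108). This neither shows nor excludes such a segment, and strain and genotype stay confounded.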
